A study of Mus musculus with 15 samples.

How the data were processed

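Bulk RNA sequencing had been done on E0771 cells, a mouse mammary carcinoma line, in 5 treatment groups of 3 libraries each, 15 libraries in total. The cells had been exposed for 5 days to an adeno-associated virus vector (AAV-Vector, the control), AAV-IFNG, IL12B, 41BBL or AAV-4II. Per the labels, RNA was extracted with TRIZOL, depleted of ribosomal RNA and made into libraries with a directional kit. The labels do not say what AAV-4II is made of, nor in what form IL12B and 41BBL were delivered, so their comparisons with AAV-Vector can also hold a difference in the vector. They also do not say whether the libraries of a group come from separate cultures, so every p-value measures only the spread between these libraries.

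The deposited table holds raw read counts per Ensembl gene, with 1 column per library, and the values are whole numbers without normalisation. The submitters' processing notes name STAR 2.7.10b. The genome build, the annotation release, the counting tool and its strand setting are not given in the sources used here, so no coordinates are printed. How reads that match several similar genes were counted, such as those of the H2, Gbp and Ifit families, is not given either. Gene symbols were taken by Ensembl identifier from the GENCODE names of mouse genes, which matched 52029 of 56953 genes (91.3%). The unmatched genes held 2.11% of the counts and stayed in every test.

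Totals ran from 9337142 to 62553276 counts per library. Genes were kept by the edgeR filter on expression by group, which left 17915 genes. The coefficient of variation that edgeR terms biological was 2.91% over the 15 libraries. Between libraries of a group, the chi-square of the counts over its degrees of freedom was 1.56 to 3.23, over genes with a joint count of at least 20. With the origin of the libraries not stated, these values cannot show how far small changes would recur between separate cultures. Values are CPM, counts relative to library sizes scaled with TMM factors, given as mean ± SD over n = 3 libraries, and log2 fold changes are given ± SE. Ratios of genes with few counts carry exact binomial (Clopper-Pearson) 95% intervals of the counts. Where a group had 0 counts, the fold is a lower bound computed against 3 counts over the group. Intervals and bounds cover counting error only, because reads without molecular identifiers are not independent molecules.

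Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in a single model of the 5 groups and all 15 libraries. The 7 comparisons were each treatment with AAV-Vector and AAV-4II with each other treatment. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The test was tested on simulated data, in which only genes of at least 1 CPM with AAV-Vector were changed. Of genes changed 2-fold, 88% to 100% were recovered, depending on the comparison, with 10 to 15 false calls in all. Of genes changed 1.25-fold, 46% to 74% were recovered. The simulated noise was independent between genes and held no difference between sequencing runs. Recovery of genes below 1 CPM was not tested.

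A set of 25 gene lists was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and its preset correlation of 0.01. Adjusted p-values of lists are over the 25 lists of a comparison. Beside it stand camera with an estimated correlation, which compares a list with other genes like the preset test, and fry, which tests whether the members of a list move on balance in 1 direction and does not compare them with other genes. In simulated data with the p53 target list moved 1.5-fold, that list was called (adjusted p = 7.1e-89) together with 1 other. The members of each list that passed the expression filter are given as tested in the report. Ddit3 and Aldoa were not found under these names. The comparisons, tests, lists, named genes and most alternatives were fixed before the data were examined.

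The named genes follow a rule. They are Ifng, Il12b, Il12a and Tnfsf9; up to 4 members of each list with the largest called change in a comparison; and the 10 genes with the largest rise and the 10 with the largest fall among called genes with at least 1 CPM in the higher group, no overlap between the libraries of both groups and a name that is not that of a predicted gene. Cd274, Irf1, B2m, H2-K1, Cxcl9, Cxcl10, Mki67 and Cdkn1a may be named in every comparison. For any gene whose groups do not overlap, chance alone gives such a separation in 10% of splits of 3 against 3 libraries. The report names a part of the genes that qualify.

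Alternatives covered DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, no filter on low counts, a stricter filter of at least 1 CPM in 3 libraries, a fit of the 6 libraries compared, library sizes without mitochondrial and rRNA genes, the replicate number as a block, and leaving out each library in turn. The library numbers in the titles repeat 3 values, so there were at least 2 sequencing runs. Vector replicate 3 and IFNG replicates 1 and 2 are out of number order, and were given their own term or left out in further alternatives. An offset for the GC content and length of each gene's longest transcript, fitted with splines of 4 degrees of freedom, and thinning of all libraries to the smallest total were added after seeing the data. Replicates of 1 number in different groups did not resemble each other (correlations of residuals from -0.0583 to 0.0398 over 30 pairs), so the numbers were not used as pairs. No library was left out of the reported values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.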

Results

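The transcriptomes of E0771 mouse mammary carcinoma cells were measured by RNA sequencing of ribosome-depleted total RNA, 5 days after delivery of immune genes. The series concerns combinations of immune genes for gene therapy of tumours, and these libraries compare the tumour cells themselves after each delivery. The labels name no other cell type. There were 3 libraries for each of 41BBL, IL12B, AAV-IFNG, AAV-4II and the control AAV-Vector. IFNG stands for interferon gamma, IL12B for the subunit shared by interleukins 12 and 23, and 41BBL for the protein of the gene Tnfsf9, a co-stimulatory ligand of T cells. Total counts were 14763500, 11554410 and 21497306 in the AAV-Vector libraries, 27492334, 9944891 and 20281029 with AAV-IFNG, and 14876939, 13418498 and 9337142 with IL12B. They were 13854679, 23529692 and 10470894 with 41BBL, and 24582758, 62553276 and 30852895 with AAV-4II. In a principal component analysis the first component held 49.5% of the variance and placed the AAV-IFNG and AAV-4II libraries at 36.4 to 49.7 and the other 9 libraries at -31.8 to -24.7. Components 2 and 3 held 8.70% and 6.31%. On component 3, IFNG replicate 2 stood apart from its group at -35.4, against -0.694 and 2.17 for replicates 1 and 3. IL12B replicate 3 stood apart on component 2 (-32.0 against -20.8 and -21.4) and on component 3 (12.9 against -0.230 and 2.12). These libraries have the lowest totals of all.

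Each delivered gene was found in the libraries its label names. Ifng (ENSMUSG00000055170.5) stood at 5.13 ± 0.907 CPM (SD, n = 3) with AAV-IFNG and 1.58 ± 0.269 CPM with AAV-4II, from 295 and 186 counts. It had 0 counts in the AAV-Vector, IL12B and 41BBL libraries, so that it was at least 87.6-fold higher with AAV-IFNG and at least 26.8-fold higher with AAV-4II than with AAV-Vector. Il12b (ENSMUSG00000004296.15) stood at 229.5 ± 1.16 CPM with IL12B and 27.9 ± 1.11 CPM with AAV-4II, against 0.109 ± 0.0786 CPM with AAV-Vector. Tnfsf9 (ENSMUSG00000035678.9) stood at 101.9 ± 4.55 CPM with 41BBL and 24.1 ± 2.58 CPM with AAV-4II, against 0.109 ± 0.0786 CPM with AAV-Vector. AAV-4II therefore carried transcripts of all 3 genes, each below its level after single delivery. Ifng was 3.27-fold lower in AAV-4II than in AAV-IFNG (95% counting interval 2.71 to 3.95), Il12b 8.29-fold lower than in IL12B (7.95 to 8.63) and Tnfsf9 4.17-fold lower than in 41BBL (3.98 to 4.37). Il12a, the partner subunit of Il12b in interleukin 12, stayed between 0.268 ± 0.117 and 0.553 ± 0.113 CPM in the 5 groups, too few counts for the test. Its ratio between AAV-4II and 41BBL was 2.19 (95% counting interval 1.20 to 4.33) and between AAV-4II and IL12B 2.03 (1.06 to 4.26). Against AAV-IFNG and AAV-Vector the libraries overlapped with those of AAV-4II, and the intervals included 1 (0.9995 to 2.98 and 0.973 to 3.05).

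**Figure D1:**
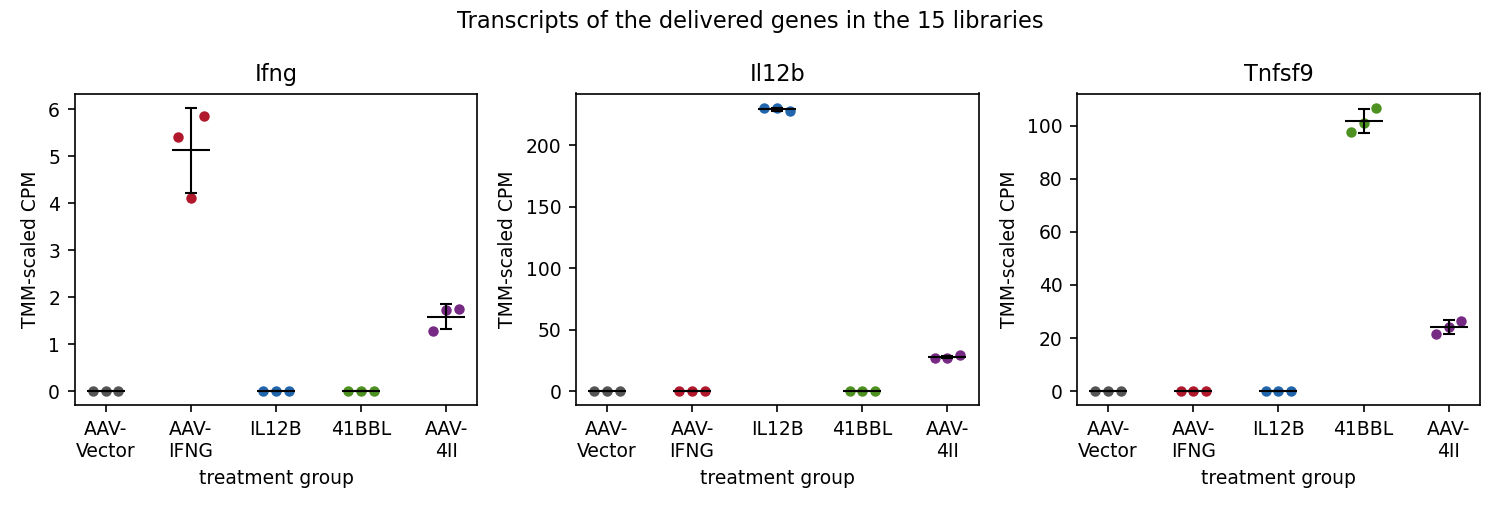
TMM-scaled CPM of Ifng, Il12b and Tnfsf9 in each of the 15 libraries by treatment group; points are libraries, and the black bars show the mean and SD of the 3 libraries. Ifng stands at 5.13 CPM with AAV-IFNG and 1.58 CPM with AAV-4II, and Il12b and Tnfsf9 are highest in the IL12B and 41BBL libraries.

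The comparison of AAV-IFNG with AAV-Vector asks what delivered interferon gamma does to the tumour cells. Genes of MHC class II antigen presentation rose from low levels. Cd74, the invariant chain of MHC class II, rose from 5.08 ± 0.26 to 402.6 ± 10.1 CPM (log2 6.30 ± 0.06 SE, adjusted p = 2.5e-49), and H2-Aa, a class II alpha chain, from 0.429 ± 0.36 to 147.9 ± 7.83 CPM (log2 8.64 ± 0.12). Nos2, the inducible nitric oxide synthase, rose from 70.8 ± 1.38 to 1256 ± 19.7 CPM (log2 4.15 ± 0.03, adjusted p = 4.0e-53). In the opposite direction, antiviral genes of the type I interferon response fell: Ifit3, which binds viral RNA complexes, went from 63.8 ± 1.9 to 5.33 ± 0.554 CPM (log2 -3.57 ± 0.07, adjusted p = 3.4e-36), and Mx1, a GTPase against viruses, from 47.2 ± 0.663 to 4.84 ± 0.421 CPM (log2 -3.32 ± 0.08). Ifnb1, the gene of interferon beta, had 1.57 ± 0.297 CPM with AAV-Vector and 1 count over the AAV-IFNG libraries, a ratio of 83.1 with a counting interval of 14.5 to 3326.

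Among 17915 genes tested, 8712 changed with AAV-IFNG, 4760 higher and 3952 lower. By at least 2-fold, 520 were higher and 618 lower. Other large rises were those of Serpina3f, a serine protease inhibitor (log2 7.64 ± 0.23), Il1a, the gene of interleukin 1 alpha (log2 6.03 ± 0.14), and Csf3, the gene of the granulocyte growth factor (log2 5.85 ± 0.16). Large falls also included the ferritin receptor gene Scara5 (log2 -4.99 ± 0.38) and Slc14a1, a urea transporter (log2 -3.06 ± 0.17).

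The interferon lists did not move as 1 block with AAV-IFNG. All 9 tested MHC class II genes rose (median log2 5.25, or 4.77 with members of 0 to 3 counts in a group taken at 3 counts, camera adjusted p = 1.7e-08). Of 21 MHC class I genes, 17 rose, 2 fell and 2 did not pass (median log2 0.45, adjusted p = 1.1e-07). The immunoproteasome subunit gene Psmb9 rose by log2 1.68 ± 0.06 and H2-K1, a class I heavy chain, by log2 0.34 ± 0.03, while the class I light chain gene B2m went from 882 ± 10.4 to 820 ± 25.8 CPM (log2 -0.10 ± 0.02). The B2m change did not pass without the 3 libraries out of number order (log2 -0.05). Of 20 interferon-inducible GTPases, 14 rose, 5 fell and 1 did not pass (median log2 1.45, adjusted p = 0.00036), with Gbp4 at log2 2.17 ± 0.06 and Igtp at log2 1.79 ± 0.04. Of 30 type I interferon-stimulated antiviral genes, 29 fell and 1 rose (median log2 -1.73, adjusted p = 3.3e-29), Ifit1 by log2 -2.95 ± 0.04. Of 21 genes of interferon gamma signalling and feedback, 7 rose, 10 fell and 4 did not pass (adjusted p = 0.53). The transcription factor genes Batf2 and Irf1 rose by log2 4.05 ± 0.13 and 1.25 ± 0.04, and Socs3, a feedback inhibitor, by log2 1.89 ± 0.04, while Sp100, of the nuclear bodies, fell by log2 -1.51 ± 0.04. Of 15 nucleic acid sensing genes, 6 rose, 8 fell and 1 did not pass (adjusted p = 0.39). The sensor gene Zbp1 rose by log2 2.05 ± 0.05, and the RNA sensors Dhx58 and Ifih1 fell by log2 -1.96 ± 0.06 and -1.58 ± 0.04.

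Chemokine and cytokine genes rose with AAV-IFNG in 19 of 26 cases, 4 fell and 3 did not pass (median log2 0.46, adjusted p = 9.4e-06). Csf2 and Il6 rose by log2 3.68 ± 0.15 and 3.03 ± 0.17. Cxcl9, which attracts T cells, rose from 4.08 ± 0.501 to 21.9 ± 1.68 CPM (log2 2.45 ± 0.11), and Cxcl10, another ligand of the same receptor, fell from 80.7 ± 2.05 to 47.6 ± 1.74 CPM (log2 -0.77 ± 0.05). Of 21 NF-kB targets, 13 rose, 4 fell and 4 did not pass (adjusted p = 0.00048), with Bcl3 at log2 1.71 ± 0.06. Of 16 immune checkpoint ligands and immunoregulatory enzymes, 9 rose, 4 fell and 3 did not pass (adjusted p = 0.064). Cd274, the ligand PD-L1, rose from 14 ± 1.45 to 18.2 ± 0.698 CPM (log2 0.40 ± 0.08, adjusted p = 6.1e-05). Of 13 genes of tryptophan, arginine and polyamine metabolism, 8 rose and 5 did not pass (adjusted p = 0.00032), Odc1 of polyamine synthesis by log2 0.61 ± 0.02. Of 10 receptors of the delivered proteins, 6 rose, 1 fell and 3 did not pass (adjusted p = 0.019, and adjusted p = 0.083 with an estimated correlation). Tnfrsf9, the receptor of 41BBL, rose by log2 1.21 ± 0.08. In the list of 3 delivered genes, 1 rose, namely Ifng, and 2 did not pass (adjusted p = 0.19).

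Growth and metabolic lists moved as well with AAV-IFNG. Of 24 genes of glycolysis and the hypoxia response, 19 rose, 1 fell and 4 did not pass (median log2 0.55, adjusted p = 7.3e-11), the peptide hormone gene Adm by log2 1.86 ± 0.03 and the lactate exporter gene Slc16a3 by log2 0.86 ± 0.03. Of 30 S phase genes, 21 rose, 3 fell and 6 did not pass (median log2 0.21, adjusted p = 0.00011), Tyms by log2 0.78 ± 0.06. Of 30 G2 and M phase genes, 7 rose, 11 fell and 12 did not pass (adjusted p = 0.073), the proliferation marker Mki67 by log2 -0.42 ± 0.03. Of 26 genes of cholesterol and lipid synthesis, 16 rose, 3 fell and 7 did not pass (median log2 0.21, adjusted p = 0.0023). The lists of cell death genes (15 rose, 10 fell and 4 did not pass, adjusted p = 0.11), p53 targets (10, 7 and 4, adjusted p = 0.73), the unfolded protein and integrated stress response (14, 6 and 3, adjusted p = 0.073), epithelial genes (2, 1 and 3, adjusted p = 0.98), mesenchymal and extracellular matrix genes (8, 13 and 5, adjusted p = 0.11) and immediate early genes (9, 7 and 2, adjusted p = 0.39) were not called. The p53 target Cdkn1a, an inhibitor of the cell cycle, rose by log2 0.69 ± 0.04. Adjusted over the list alone, 8 rose and 10 fell of interferon gamma signalling, 13 and 5 of NF-kB targets, 16 and 10 of cell death genes, 10 and 8 of p53 targets, 14 and 7 of the stress response, 20 and 1 of glycolysis and 9 and 8 of immediate early genes. In the other lists the counts adjusted over the list alone were those given.

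Markers of other cell types and of RNA quality moved in part with AAV-IFNG. Of 8 tested leukocyte markers, 4 rose, 1 fell and 3 did not pass (adjusted p = 0.19), with Csf1r, a macrophage growth factor receptor, at 31.1 ± 1.18 against 1.83 ± 0.222 CPM. Of 11 fibroblast and endothelial markers, 2 rose, 6 fell and 3 did not pass (adjusted p = 0.11), and the matrix protein gene Dpt fell by log2 -1.57 ± 0.10. Of 14 mitochondrially encoded genes, 6 rose and 8 did not pass (median log2 0.38, adjusted p = 0.018, and adjusted p = 0.34 with an estimated correlation). That call ended without IFNG replicate 3 (adjusted p = 0.0518) and without Vector replicate 3 (adjusted p = 0.0506). Mitochondrial genes held 2.57 ± 0.046% of counts with AAV-IFNG and 2.41 ± 0.103% with AAV-Vector. IFNG replicates 1 and 2 and Vector replicate 3 have library numbers out of order with the rest.

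**Figure D2:**
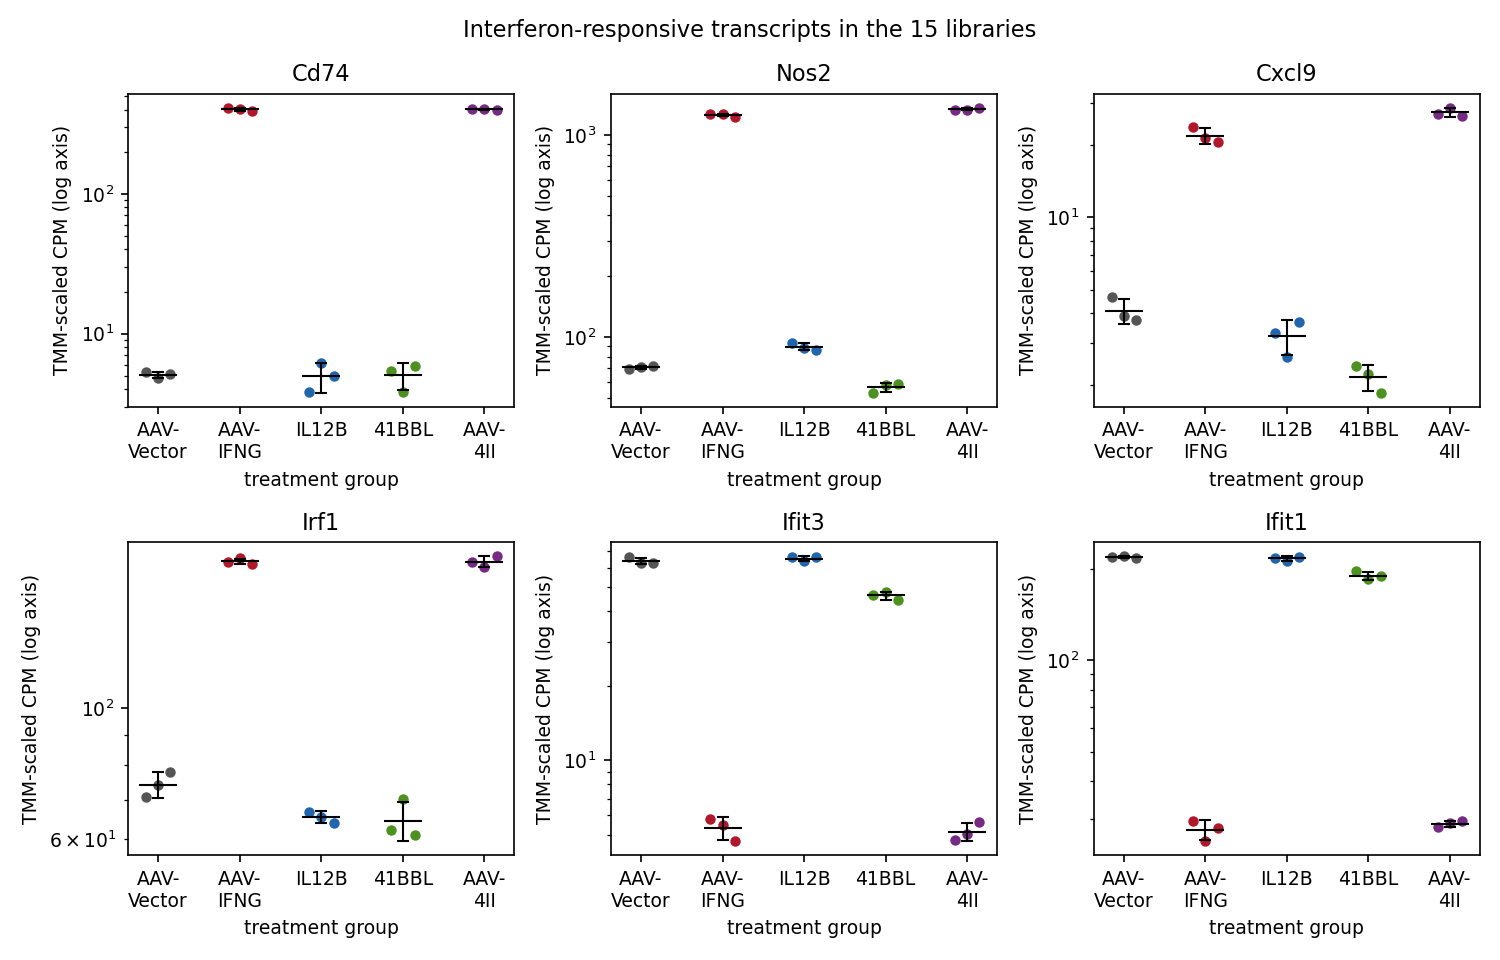
TMM-scaled CPM on a log axis of Cd74, Nos2, Cxcl9, Irf1, Ifit3 and Ifit1 in each of the 15 libraries by treatment group; points are libraries, and the black bars show the mean and SD of the 3 libraries. Cd74, Nos2, Cxcl9 and Irf1 are higher, and Ifit3 and Ifit1 lower, in every AAV-IFNG and AAV-4II library than in any library of the other groups.

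The comparison of IL12B with AAV-Vector asks what delivered Il12b changes in the tumour cells. Il12b itself rose 2258-fold (95% counting interval 967 to 6957). Among the other large rises were those of Prss35, a serine protease family member, from 2.01 ± 0.381 to 18.5 ± 1.4 CPM (log2 3.19 ± 0.14, adjusted p = 1.4e-22), Scn11a, a sodium channel gene, from 2.03 ± 0.452 to 9.23 ± 0.284 CPM (log2 2.22 ± 0.15) and Rab15, a vesicle transport GTPase, from 2.54 ± 0.336 to 11.2 ± 0.592 CPM (log2 2.10 ± 0.13). Genes of cholesterol synthesis rose together, Cyp51 from 56.1 ± 3.03 to 74.5 ± 2.28 CPM (log2 0.41 ± 0.04, adjusted p = 6.6e-10). Of 20 interferon-inducible GTPases, 8 fell and 12 did not pass, Gbp2 falling from 56 ± 1.59 to 41.1 ± 2.85 CPM (log2 -0.46 ± 0.05, adjusted p = 3.7e-10).

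With IL12B, 1907 of 17915 genes changed, 1045 higher and 862 lower. By at least 2-fold, 123 were higher and 17 lower, and DESeq2 called 73 in all at that size. The changes were small, with a median absolute log2 change of 0.23 among the called genes. The falls named by the rule were led by Grhl2, an epithelial transcription factor gene, from 1.22 ± 0.4 to 0.321 ± 0.127 CPM (log2 -1.78 ± 0.43), and Elovl7, of fatty acid elongation, from 2.69 ± 0.715 to 0.948 ± 0.275 CPM (log2 -1.42 ± 0.26).

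Of 26 genes of cholesterol and lipid synthesis, 20 rose with IL12B and 6 did not pass (median log2 0.22, camera adjusted p = 5.7e-16), among them Insig1 (log2 0.37 ± 0.04) and Msmo1 (log2 0.36 ± 0.04). Of 20 interferon-inducible GTPases, 8 fell and 12 did not pass (median log2 -0.24, adjusted p = 1.5e-08), with Gbp5 at log2 -0.36 ± 0.05. Of 21 MHC class I genes, 8 fell and 13 did not pass (median log2 -0.10, adjusted p = 0.00013), the peptide transporter gene Tap1 by log2 -0.31 ± 0.04. Of 21 genes of interferon gamma signalling, 1 rose, 4 fell and 16 did not pass (adjusted p = 0.0095), Parp14 by log2 -0.19 ± 0.03 and Irf1 by log2 -0.19 ± 0.04. The Irf1 change did not pass without Vector replicate 3 or without the 3 libraries out of number order (log2 -0.14 in both cases). Of 30 type I interferon-stimulated antiviral genes, 6 fell and 24 did not pass (median log2 -0.05, adjusted p = 0.011), Oas3 by log2 -0.20 ± 0.03. Of 21 NF-kB targets, 2 rose, 7 fell and 12 did not pass (adjusted p = 0.0031), Relb by log2 -0.28 ± 0.05. The 9 MHC class II genes did not pass (adjusted p = 0.97).

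The calls of 8 further lists with IL12B did not hold with an estimated correlation. The list of 3 delivered genes had 1 rising member, Il12b, and 2 that did not pass (adjusted p = 0.0059, and adjusted p = 0.059 with an estimated correlation). Of 15 nucleic acid sensing genes, 2 fell and 13 did not pass (adjusted p = 0.020, and adjusted p = 0.059 with an estimated correlation). Of 24 glycolysis and hypoxia genes, 11 rose, 1 fell and 12 did not pass, Adm by log2 0.77 ± 0.04 (adjusted p = 0.00048, and adjusted p = 0.065 with an estimated correlation). Of 6 epithelial genes, 1 fell and 5 did not pass (adjusted p = 0.023, and adjusted p = 0.065 with an estimated correlation). Of 18 immediate early genes, 8 rose, 1 fell and 9 did not pass, Dusp1, a phosphatase, by log2 0.57 ± 0.03 (adjusted p = 0.0010, and adjusted p = 0.071 with an estimated correlation). Of 26 mesenchymal and matrix genes, 7 rose, 4 fell and 15 did not pass, the matrix protein gene Tnc by log2 1.15 ± 0.13 (adjusted p = 0.020, and adjusted p = 0.11 with an estimated correlation). This call also ended without IL12B replicate 2 (adjusted p = 0.0615) and without Vector replicate 2 (adjusted p = 0.0646). Of 30 G2 and M phase genes, 1 rose, 2 fell and 27 did not pass (adjusted p = 0.042, and adjusted p = 0.12 with an estimated correlation). That call ended without IL12B replicate 1 (adjusted p = 0.0863), IL12B replicate 2 (adjusted p = 0.0888), Vector replicate 1 (adjusted p = 0.0593) and Vector replicate 2 (adjusted p = 0.123).

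Other lists were not called with IL12B. They were the receptors (0 rose, 1 fell and 9 did not pass, adjusted p = 0.29), chemokines and cytokines (5, 3 and 18, adjusted p = 0.97) and checkpoint ligands and immunoregulatory enzymes (2, 3 and 11, adjusted p = 0.42). The others were cell death genes (6, 7 and 16, adjusted p = 0.41), S phase genes (0, 2 and 28, adjusted p = 0.053), p53 targets (2, 3 and 16, adjusted p = 0.11), the stress response (2, 4 and 17, adjusted p = 0.80) and tryptophan, arginine and polyamine metabolism (2, 2 and 9, adjusted p = 0.97). Tgfb2, the gene of a transforming growth factor, rose by log2 0.98 ± 0.11, and Cd274 stood at 11.9 ± 0.49 against 14 ± 1.45 CPM without passing. With IL12B, adjusted over the list alone, 11 GTPases fell, 9 MHC class I genes fell and 1 rose, 10 antiviral genes fell, 12 NF-kB targets fell and 2 rose, and 14 glycolysis genes rose and 2 fell. The counts adjusted over the list alone were 1 and 5 for interferon gamma signalling, 1 and 4 for nucleic acid sensing, 8 and 6 for chemokines, 3 and 3 for checkpoint ligands, 7 and 7 for cell death, 1 and 3 for G2 and M phase, 2 and 4 for p53 targets, 5 and 5 for the stress response, 3 and 2 for tryptophan metabolism, 9 and 5 for matrix genes and 4 and 0 for mitochondrial genes. The remaining lists had the counts given.

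Among markers of other cell types with IL12B, 4 of 11 fibroblast and endothelial markers rose and 7 did not pass (adjusted p = 0.0019). Dpt stood at 46.2 ± 0.507 against 18.5 ± 0.616 CPM (log2 1.32 ± 0.07), and Pdgfra, a receptor of platelet-derived growth factor, rose by log2 0.24 ± 0.03. Of 8 leukocyte markers, 1 rose, namely Csf1r (log2 1.70 ± 0.16), 2 fell and 5 did not pass (adjusted p = 0.97). Of 14 mitochondrially encoded genes, 3 rose and 11 did not pass (adjusted p = 0.020, and adjusted p = 0.38 with an estimated correlation). This call ended without IL12B replicate 3 (adjusted p = 0.315), Vector replicate 1 (adjusted p = 0.0589) and Vector replicate 3 (adjusted p = 0.118). Mitochondrial genes held 2.54 ± 0.29% of counts with IL12B.

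The comparison of 41BBL with AAV-Vector asks what the delivered co-stimulatory ligand changes in the tumour cells. Tnfsf9 rose 996.5-fold (95% counting interval 427 to 3070), and little else moved far. Type I interferon-stimulated antiviral genes fell slightly, Ifit3 from 63.8 ± 1.9 to 46.3 ± 1.72 CPM (log2 -0.45 ± 0.05, adjusted p = 2.7e-08) and Isg15, a ubiquitin-like modifier, from 129 ± 2.48 to 99.4 ± 6.5 CPM (log2 -0.37 ± 0.04). Hmgcs1, of cholesterol synthesis, rose from 56.2 ± 0.812 to 71.8 ± 1.63 CPM (log2 0.35 ± 0.04, adjusted p = 7.5e-08). Cxcl9 fell from 4.08 ± 0.501 to 2.17 ± 0.274 CPM (log2 -0.88 ± 0.17, adjusted p = 0.00049).

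With 41BBL, 1486 of 17915 genes changed, 785 higher and 701 lower, with a median absolute log2 change of 0.16. By at least 2-fold, 17 were higher and 4 lower, while DESeq2 called 1 gene at that size, no filter gave 39 genes and the offset for GC content and length 13. DESeq2 called 610 higher and 863 lower in all. Without Vector replicate 3 there were 693 changed genes and without 41BBL replicate 1 there were 763. Without Vector replicate 2, 33 genes changed at least 2-fold. The run term gave 979 genes, leaving out the 3 libraries out of number order 652, thinning to the smallest total 871 and the offset for GC content and length 667, of which 480 were among those called without it. The largest rises after Tnfsf9 included the small RNA genes Rny1 (log2 1.37 ± 0.19) and Rny3 (log2 1.25 ± 0.21), and the falls Tmprss2, a membrane protease gene (log2 -0.87 ± 0.19).

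Of 30 type I interferon-stimulated antiviral genes, 18 fell with 41BBL and 12 did not pass (median log2 -0.13, camera adjusted p = 1.5e-11). Of 21 genes of interferon gamma signalling, 10 fell and 11 did not pass (median log2 -0.11, adjusted p = 2.0e-07), Stat2 by log2 -0.31 ± 0.03. Of 20 interferon-inducible GTPases, 7 fell and 13 did not pass (median log2 -0.22, adjusted p = 2.0e-09), Igtp by log2 -0.45 ± 0.05. Of 21 MHC class I genes, 9 fell and 12 did not pass (median log2 -0.12, adjusted p = 9.5e-05), Tap2 by log2 -0.21 ± 0.05. The Tap2 change did not pass with the offset for GC content and length (log2 -0.13), without Vector replicate 3 or without the 3 libraries out of number order (log2 -0.17 in both cases). Of 26 chemokines and cytokines, 1 rose, 3 fell and 22 did not pass (adjusted p = 0.0013). The riser was Ccl5, which attracts T cells (log2 0.34 ± 0.04). Cxcl9, Cxcl10 and Csf1 fell by log2 -0.88 ± 0.17, -0.195 ± 0.04 and -0.14 ± 0.03. Of 26 genes of cholesterol and lipid synthesis, 11 rose, 2 fell and 13 did not pass (median log2 0.13, adjusted p = 2.0e-07). Of 30 S phase genes, 8 fell and 22 did not pass (adjusted p = 0.00012), and of 30 G2 and M phase genes, 5 rose and 25 did not pass (adjusted p = 0.00079), with Mcm2 at log2 -0.16 ± 0.03 and Hmmr at log2 0.16 ± 0.03. The Hmmr change did not pass with the offset (log2 0.09). The medians of the cholesterol, GTPase, MHC class I and antiviral lists had the same sign with IL12B as with 41BBL. Both comparisons use the same AAV-Vector libraries. For these lists, effects of the delivered genes therefore cannot be told apart from noise in those libraries or a difference in the vector.

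The calls of 3 lists with 41BBL did not hold with an estimated correlation. Of 24 glycolysis and hypoxia genes, 2 rose, 10 fell and 12 did not pass, Gapdh by log2 -0.18 ± 0.02 (adjusted p = 0.00022, and adjusted p = 0.077 with an estimated correlation). The list of 3 delivered genes had 1 rising member, Tnfsf9, and 2 that did not pass (adjusted p = 0.025, and adjusted p = 0.12 with an estimated correlation). Its call ended without 41BBL replicate 3 (adjusted p = 0.0705), Vector replicate 2 (adjusted p = 0.149) and Vector replicate 3 (adjusted p = 0.0816). Of 14 mitochondrially encoded genes, 5 rose and 9 did not pass, the ribosomal RNA gene mt-Rnr2 by log2 0.52 ± 0.06 (adjusted p = 0.00019, and adjusted p = 0.21 with an estimated correlation). With the offset for GC content and length, the adjusted p of this list was 0.62. Mitochondrial genes held 2.99 ± 0.17% of counts with 41BBL.

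Other lists were not called with 41BBL. They were the receptors (1 rose, 0 fell and 9 did not pass, adjusted p = 0.99), MHC class II genes (0, 0 and 9, adjusted p = 0.99), nucleic acid sensing (1, 2 and 12, adjusted p = 0.10), checkpoint ligands and immunoregulatory enzymes (2, 2 and 12, adjusted p = 0.45) and NF-kB targets (3, 2 and 16, adjusted p = 0.41). The others were cell death genes (2, 5 and 22, adjusted p = 0.98), p53 targets (1, 2 and 18, adjusted p = 0.93), the stress response (3, 4 and 16, adjusted p = 0.86), tryptophan, arginine and polyamine metabolism (1, 1 and 11, adjusted p = 0.99) and epithelial genes (0, 0 and 6, adjusted p = 0.11). Matrix genes (0, 3 and 23, adjusted p = 0.45), immediate early genes (3, 3 and 12, adjusted p = 0.99), leukocyte markers (0, 0 and 8, adjusted p = 0.45) and fibroblast and endothelial markers (0, 1 and 10, adjusted p = 0.45) were not called either. With 41BBL, adjusted over the list alone, 22 antiviral genes, 12 GTPases and 11 S phase genes fell with none rising, 12 MHC class I genes fell and 1 rose, 14 cholesterol genes rose and 2 fell, and 8 G2 and M phase genes rose and 1 fell. The counts adjusted over the list alone were 1 and 5 for chemokines, 3 and 11 for glycolysis, 8 and 0 for mitochondrial genes, 1 and 3 for nucleic acid sensing, 2 and 3 for checkpoint ligands, 5 and 6 for cell death, 3 and 3 for p53 targets, 6 and 4 for the stress response, 2 and 3 for tryptophan metabolism, 1 and 5 for matrix genes and 4 and 3 for immediate early genes. The remaining lists had the counts given.

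The comparison of AAV-4II with AAV-Vector asks what the combined delivery changes. MHC class II genes rose here too, Cd74 to 402.9 ± 3.21 CPM (log2 6.30 ± 0.06, adjusted p = 1.8e-49) and H2-Aa to 159.9 ± 4.63 CPM (log2 8.75 ± 0.11). Nos2 reached 1345 ± 17.3 CPM (log2 4.25 ± 0.03), and the PD-L1 gene Cd274 rose from 14 ± 1.45 to 23 ± 0.489 CPM (log2 0.73 ± 0.07). Antiviral genes fell, Ifit3 to 5.15 ± 0.429 CPM (log2 -3.63 ± 0.06, adjusted p = 3.7e-39) and Mx1 to 5.47 ± 0.466 CPM (log2 -3.13 ± 0.07). Ifnb1 fell from 1.57 ± 0.297 to 0.123 ± 0.04 CPM (log2 -3.66 ± 0.40).

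With AAV-4II, 8004 of 17915 genes changed, 4426 higher and 3578 lower. By at least 2-fold, 508 were higher and 444 lower. Further large changes were the rises of Serpina3f (log2 7.71 ± 0.22), Il1a (log2 5.99 ± 0.13) and Csf3 (log2 5.94 ± 0.16) and the falls of Scara5 (log2 -4.42 ± 0.29) and Oasl1, an antiviral gene (log2 -2.93 ± 0.06). The calls of both AAV-IFNG and AAV-4II against AAV-Vector covered 3611 genes higher in both, 2747 lower in both and 54 in opposite directions. Independent lists of these sizes would share 1176, 789.3 and 1927. Across 15048 genes, which are not independent replicates, the log2 changes of AAV-IFNG and AAV-4II correlated with r = 0.91, against 0.58 in simulations of unchanged groups that share their controls. The covariance was 0.26 against 0.0117 in the simulations. In unchanged groups r comes from noise alone and is set by the shared controls, while treatment effects also shape the real r. The real and simulated r are therefore not comparable in size, and the covariances are. IFNG and IL12B shared 553 higher and 376 lower genes with 483 in opposite directions, where independent lists would share 277.7, 190.2 and 459.6. Their changes correlated with r = 0.20 (0.48 in the simulations), and their covariance of 0.0278 was above the 0.0117 of the simulations. For IFNG and 41BBL the numbers were 208, 140 and 768, against 208.6, 154.6 and 359.4, with r = -0.04 against 0.51 in the simulations and a covariance of -0.00493 against 0.0118. The log2 changes followed the GC content of genes in opposite directions, with Spearman correlations of 0.19 for AAV-IFNG and -0.41 for 41BBL. Whether that trend adds to the 768 genes was not tested, since the offset was applied only to genes shared in the same direction. The 348 genes shared in the same direction became 169 without Vector replicate 3, 201 without 41BBL replicate 1, 151 without the 3 libraries out of number order, 200 with thinning and 215 with the offset for GC content and length. IL12B and 41BBL shared 137 higher and 132 lower genes with 110 in opposite directions, against 45.8, 33.7 and 78.7 for independent lists. Their covariance of 0.01325 was close to the 0.0118 of the simulations, so much of it may come from the shared controls. For IL12B and AAV-4II the numbers were 516, 346 and 497, against 258.2, 172.2 and 421.7. Their covariance was 0.02515 against 0.0118. For 41BBL and AAV-4II the numbers were 351, 208 and 470, against 193.9, 140 and 330. Their covariance of 0.00997 was below the 0.0117 of the simulations. The covariances of these last pairs include Il12b and Tnfsf9, each delivered in both groups of its pair. These comparisons use the same 3 AAV-Vector libraries, too few to split, and noise in them moves all such changes in the same direction.

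With AAV-4II, all 9 MHC class II genes rose (median log2 5.39, or 4.94 with members of 0 to 3 counts in a group taken at 3 counts, camera adjusted p = 1.8e-10). Of 21 MHC class I genes, 19 rose and 2 did not pass (median log2 0.38, adjusted p = 2.6e-09), Psmb9 by log2 1.72 ± 0.06 and B2m by log2 0.12 ± 0.02. Of 20 interferon-inducible GTPases, 16 rose, 3 fell and 1 did not pass (median log2 1.44, adjusted p = 1.4e-08), Gbp4 by log2 2.60 ± 0.06. Of 30 type I antiviral genes, 29 fell and 1 rose (median log2 -1.73, adjusted p = 5.3e-36). Of 26 chemokines and cytokines, 19 rose, 3 fell and 4 did not pass (median log2 0.57, adjusted p = 5.1e-07), Cxcl9 by log2 2.76 ± 0.10, while Cxcl10 fell by log2 -0.53 ± 0.04. Of 16 checkpoint ligands and immunoregulatory enzymes, 10 rose, 3 fell and 3 did not pass (adjusted p = 0.0041). Of 21 NF-kB targets, 12 rose, 6 fell and 3 did not pass (adjusted p = 0.00046). Of 13 genes of tryptophan, arginine and polyamine metabolism, 9 rose and 4 did not pass (adjusted p = 7.4e-05). Of 24 glycolysis and hypoxia genes, 20 rose, 1 fell and 3 did not pass (median log2 0.44, adjusted p = 7.8e-12), Adm by log2 1.33 ± 0.03.

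Further calls with AAV-4II were those of 26 genes of cholesterol and lipid synthesis (17 rose, 3 fell and 6 did not pass, adjusted p = 0.0020), 29 cell death genes (17, 8 and 4, adjusted p = 0.010), the 3 delivered genes (3, 0 and 0, adjusted p = 1.3e-05), 10 receptors (7, 2 and 1, adjusted p = 0.0091) and 30 S phase genes (17, 4 and 9, adjusted p = 0.027). The S phase call ended with the offset for GC content and length (adjusted p = 0.0674). The death receptor gene Fas rose by log2 1.03 ± 0.06. The stress response (10, 3 and 10, adjusted p = 0.029) had adjusted p = 0.069 with an estimated correlation, and mesenchymal and matrix genes (8, 15 and 3, adjusted p = 0.040) had adjusted p = 0.14 with an estimated correlation. With the offset for GC content and length both calls ended (adjusted p = 0.0893 and adjusted p = 0.0542). In these lists the cystine transporter gene Slc7a11 rose by log2 1.05 ± 0.05 and Col6a2, a collagen gene, fell by log2 -1.47 ± 0.03. Not called were interferon gamma signalling (9, 10 and 2, adjusted p = 0.81), nucleic acid sensing (6, 6 and 3, adjusted p = 0.50), G2 and M phase (6, 10 and 14, adjusted p = 0.13), p53 targets (7, 4 and 10, adjusted p = 0.56), epithelial genes (2, 2 and 2, adjusted p = 0.93) and immediate early genes (8, 5 and 5, adjusted p = 0.19). Adjusted over the list alone, the counts were 7 and 7 for nucleic acid sensing, 18 and 4 for S phase genes and 4 and 2 for leukocyte markers, and for the other lists those given.

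With AAV-4II, 14 of 14 mitochondrially encoded genes rose (median log2 0.88, adjusted p = 8.4e-08, and adjusted p = 0.054 with an estimated correlation), mt-Nd1 of respiratory complex I by log2 1.25 ± 0.03. Mitochondrial genes held 3.96 ± 0.217% of counts with AAV-4II against 2.41 ± 0.103% with AAV-Vector. Without the mitochondrial ribosomal and transfer RNA genes the shares were 2.12 ± 0.0197% and 1.34 ± 0.014%. Of 11 fibroblast and endothelial markers, 2 rose, 7 fell and 2 did not pass (adjusted p = 0.014), Dpt by log2 -1.97 ± 0.09. Of 8 leukocyte markers, 4 rose, 1 fell and 3 did not pass (adjusted p = 0.11), Csf1r by log2 3.42 ± 0.12 and S100a8, abundant in neutrophils, by log2 3.08 ± 0.17.

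**Figure D3:**
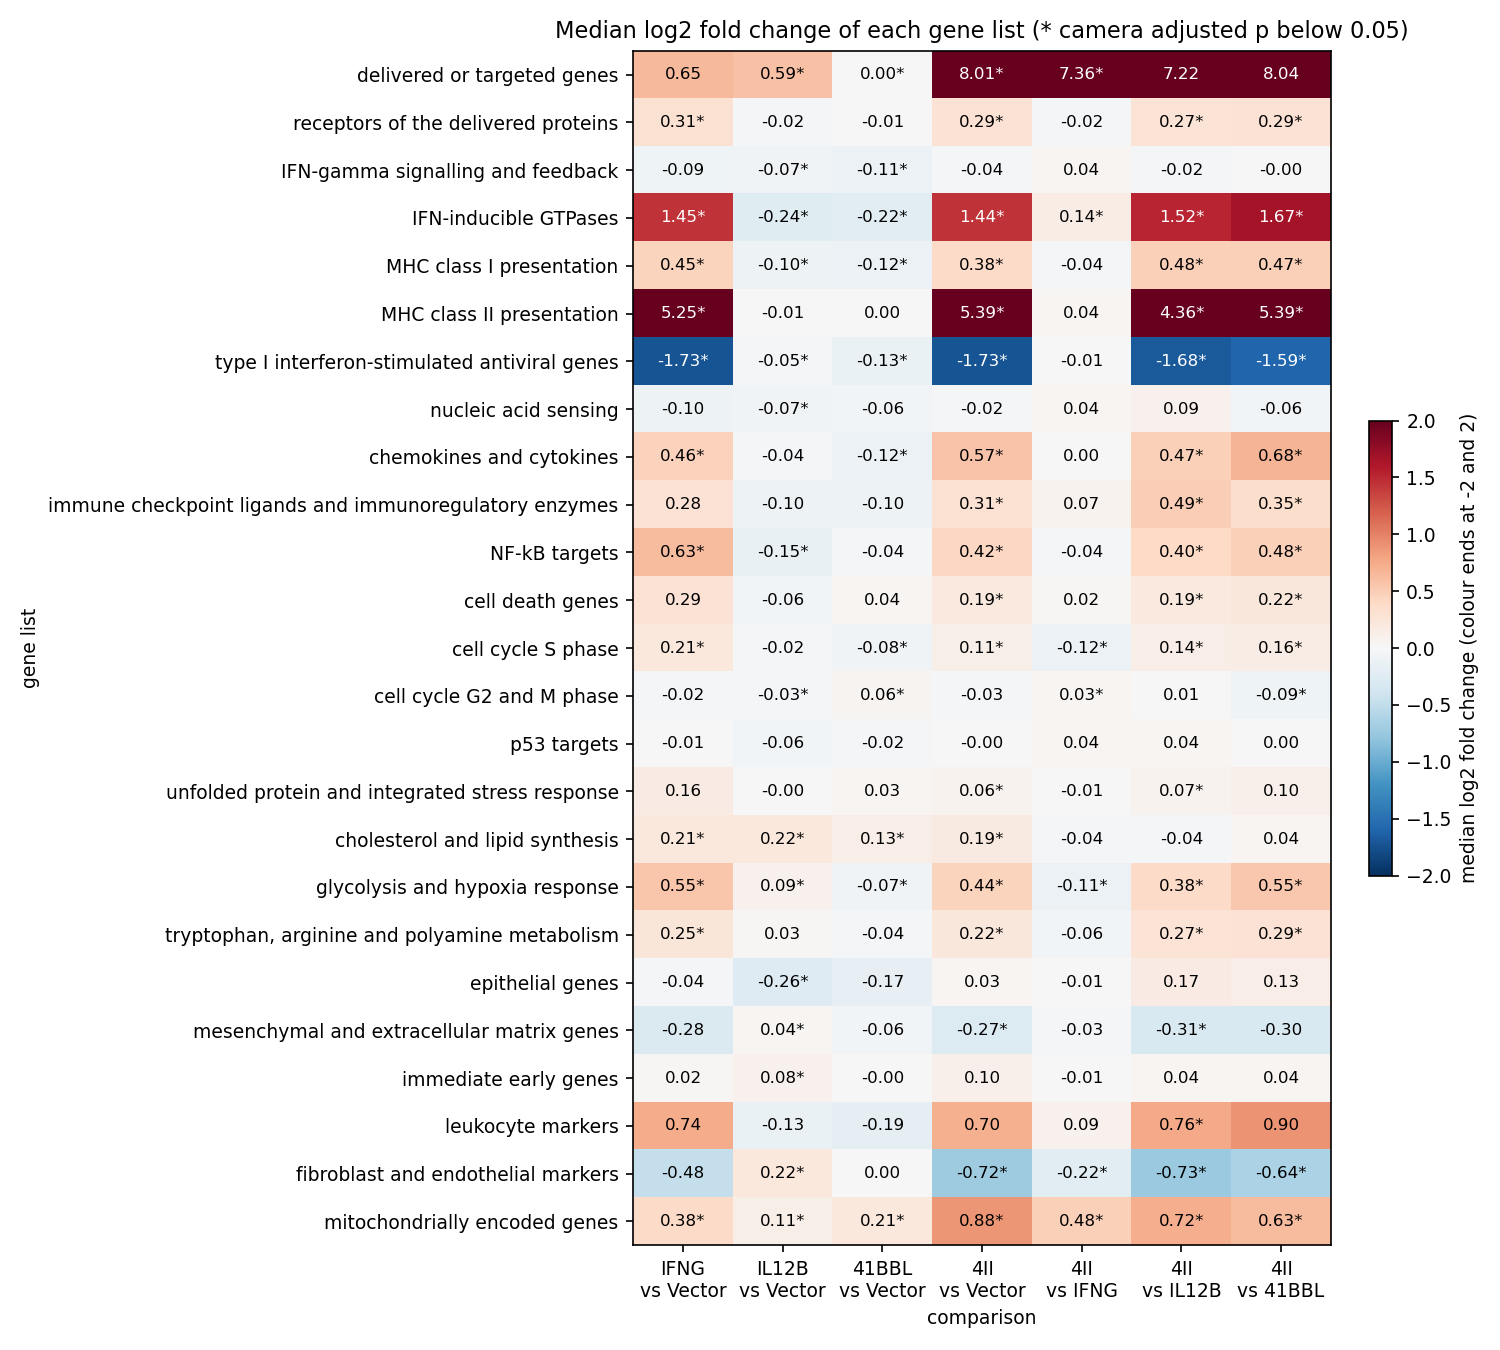
Median fitted log2 fold change over the tested members of each of the 25 gene lists (vertical axis) in each of the 7 comparisons (horizontal axis); colours end at -2 and 2, and asterisks mark a camera adjusted p below 0.05 with the preset correlation. MHC class II genes have medians of 5.25 and 5.39, and type I antiviral genes of -1.73 in both cases, with AAV-IFNG and AAV-4II against AAV-Vector. Medians of the delivered genes and of MHC class II genes hold members near 0 counts.

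The comparison of AAV-4II with AAV-IFNG asks what the combination adds to interferon gamma, although the Ifng transcript was 3.27-fold lower in AAV-4II. Il12b and Tnfsf9 rose as delivered, Il12b 170-fold (95% counting interval 89.5 to 372) and Tnfsf9 by a ratio of 670.7 (185.5 to 5541). Interferon-inducible GTPases were somewhat higher, Gbp8 at 12.4 ± 0.763 against 7.37 ± 1.33 CPM (log2 0.73 ± 0.12, adjusted p = 1.0e-05) and Gbp4 at 76.3 ± 2.16 against 56.3 ± 1.16 CPM (log2 0.44 ± 0.04). Cd274 (log2 0.33 ± 0.07), Cxcl9 (log2 0.32 ± 0.07) and B2m (log2 0.22 ± 0.02) were higher as well. Irf1 stood at 178 ± 3.85 against 178 ± 1.88 CPM and did not pass.

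Of 17915 genes, 4042 differed between AAV-4II and AAV-IFNG, 1790 higher and 2252 lower, with a median absolute log2 change of 0.19. By at least 2-fold, 40 were higher and 25 lower, while DESeq2 called 6 at that size, no filter gave 109 and the stricter filter 35. Without a filter the split of all called genes was 1834 higher and 1461 lower. The run term gave 2560 genes, thinning 2511 and leaving out the 3 libraries out of number order 1808. Among the largest changes named by the rule were the rise of mt-Rnr2 (log2 0.90 ± 0.06) and the fall of Sla, an adaptor protein gene (log2 -0.93 ± 0.21), which did not pass after thinning (log2 -0.90).

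Of 20 interferon-inducible GTPases, 11 were higher in AAV-4II than in AAV-IFNG and 9 did not pass (median log2 0.14, adjusted p = 2.4e-06). Of 30 S phase genes, 16 were lower and 14 did not pass (median log2 -0.12, adjusted p = 2.4e-06), Mcm5 by log2 -0.26 ± 0.03. The calls of 5 lists did not hold with an estimated correlation. They were the 3 delivered genes (2 higher, 1 lower and 0 not passed, adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation), G2 and M phase genes (10, 1 and 19, adjusted p = 0.034, and adjusted p = 0.13 with an estimated correlation), glycolysis and hypoxia genes (2, 14 and 8, adjusted p = 9.2e-05, and adjusted p = 0.12 with an estimated correlation), fibroblast and endothelial markers (0, 4 and 7, adjusted p = 0.025, and adjusted p = 0.12 with an estimated correlation) and mitochondrially encoded genes (13, 0 and 1, adjusted p = 8.6e-11, and adjusted p = 0.10 with an estimated correlation). Adm was lower by log2 -0.54 ± 0.03. The G2 and M phase call ended without 4II replicate 3 (adjusted p = 0.0614), IFNG replicate 1 (adjusted p = 0.0601) and IFNG replicate 3 (adjusted p = 0.0526), and with the offset for GC content and length (adjusted p = 0.226). The fibroblast call ended without IFNG replicate 1 (adjusted p = 0.0993).

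Not called between AAV-4II and AAV-IFNG were type I antiviral genes (6 higher, 6 lower and 18 not passed, adjusted p = 0.90), MHC class I genes (1, 6 and 14, adjusted p = 0.29), MHC class II genes (1, 0 and 8, adjusted p = 0.90), interferon gamma signalling (4, 1 and 16, adjusted p = 0.31), nucleic acid sensing (3, 2 and 10, adjusted p = 0.41), chemokines (8, 4 and 14, adjusted p = 0.90), checkpoint ligands (5, 1 and 10, adjusted p = 0.078) and NF-kB targets (1, 5 and 15, adjusted p = 0.32). Nor were cell death (8, 7 and 14, adjusted p = 0.85), p53 targets (4, 5 and 12, adjusted p = 0.52) and the stress response (8, 5 and 10, adjusted p = 0.90). Nor were cholesterol synthesis (6, 7 and 13, adjusted p = 0.41), tryptophan metabolism (3, 1 and 9, adjusted p = 0.90), receptors (1, 1 and 8, adjusted p = 0.90), epithelial genes (0, 0 and 6, adjusted p = 0.90), matrix genes (1, 6 and 19, adjusted p = 0.32), immediate early genes (4, 7 and 7, adjusted p = 0.90) and leukocyte markers (0, 1 and 7, adjusted p = 0.90). Csf1r was lower by log2 -0.65 ± 0.07. Adjusted over the list alone, 13 GTPases were higher and 0 lower, and the counts were 2 and 1 for receptors, 5 and 1 for interferon gamma signalling, 1 and 7 for MHC class I, 0 and 0 for MHC class II, 9 and 7 for chemokines, 3 and 6 for NF-kB targets, 11 and 3 for G2 and M phase, 5 and 5 for p53 targets, 8 and 7 for the stress response, 7 and 8 for cholesterol synthesis, 3 and 15 for glycolysis, 2 and 6 for matrix genes and 5 and 7 for immediate early genes. The remaining lists had the counts given.

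The comparisons of AAV-4II with IL12B and with 41BBL ask what the combination adds to the other single genes. Cd74 stood at 402.9 ± 3.21 CPM against 4.99 ± 1.2 with IL12B (log2 6.35 ± 0.06) and 5.04 ± 1.08 with 41BBL (log2 6.41 ± 0.06). Serpina3f was at least 287.5-fold higher than with IL12B, where it had 0 counts. Cxcl9 was higher by log2 3.12 ± 0.11 and 3.64 ± 0.11, and Ifit3 lower by log2 -3.66 ± 0.06 and -3.18 ± 0.07. Against IL12B, 7981 of 17915 genes differed, 4307 higher and 3674 lower, with 449 and 579 by at least 2-fold. Against 41BBL, 8516 differed, 4530 higher and 3986 lower, with 523 and 480 by at least 2-fold. Dpt was lower by log2 -3.29 ± 0.08 against IL12B and -1.97 ± 0.09 against 41BBL.

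Against IL12B, all 9 MHC class II genes were higher (median log2 4.36, adjusted p = 1.7e-10), as were 17 of 20 GTPases, with 1 lower and 2 not passed (median log2 1.52, adjusted p = 4.5e-12), and 17 of 21 MHC class I genes, with 1 lower and 3 not passed (adjusted p = 1.4e-10). Of 30 antiviral genes, 29 were lower and 1 higher (median log2 -1.68, adjusted p = 3.7e-33). Further calls were chemokines (17 higher, 4 lower and 5 not passed, adjusted p = 5.5e-06), checkpoint ligands (10, 3 and 3, adjusted p = 0.00054), NF-kB targets (14, 4 and 3, adjusted p = 8.4e-07), cell death (16, 6 and 7, adjusted p = 0.0068), receptors (7, 2 and 1, adjusted p = 0.0068), S phase (18, 3 and 9, adjusted p = 0.0021), glycolysis and hypoxia (21, 2 and 1, adjusted p = 5.6e-10), tryptophan metabolism (8, 1 and 4, adjusted p = 0.00037) and fibroblast and endothelial markers (1, 8 and 2, adjusted p = 0.00054). Calls without support from an estimated correlation were the stress response (11, 4 and 8, adjusted p = 0.028, and adjusted p = 0.073 with an estimated correlation), matrix genes (5, 14 and 7, adjusted p = 0.0068, and adjusted p = 0.068 with an estimated correlation), mitochondrially encoded genes (11, 0 and 3, adjusted p = 3.9e-06, and adjusted p = 0.087 with an estimated correlation) and leukocyte markers (5, 0 and 3, adjusted p = 0.048, and adjusted p = 0.087 with an estimated correlation). The leukocyte call ended without 4II replicate 1 (adjusted p = 0.0501), 4II replicate 2 (adjusted p = 0.0579) and IL12B replicate 1 (adjusted p = 0.0543). With the offset for GC content and length it also ended (adjusted p = 0.0564), as did that of the stress response (adjusted p = 0.0723). Not called were the delivered genes (2, 1 and 0, adjusted p = 0.12), interferon gamma signalling (9, 10 and 2, adjusted p = 0.79), nucleic acid sensing (6, 5 and 4, adjusted p = 0.92), G2 and M phase (10, 9 and 11, adjusted p = 0.72), p53 targets (8, 4 and 9, adjusted p = 0.34), cholesterol synthesis (3, 10 and 13, adjusted p = 0.091), epithelial genes (2, 1 and 3, adjusted p = 0.34) and immediate early genes (6, 6 and 6, adjusted p = 0.97). Adjusted over the list alone, the counts were 16 and 7 for cell death, 10 and 10 for G2 and M phase, 4 and 10 for cholesterol synthesis, 9 and 1 for tryptophan metabolism and 6 and 7 for immediate early genes, and for the other lists those given.

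Against 41BBL, all 9 MHC class II genes were higher (median log2 5.39, or 4.95 with members of 0 to 3 counts in a group taken at 3 counts, adjusted p = 4.2e-10), as were 16 of 20 GTPases, with 2 lower and 2 not passed (median log2 1.67, adjusted p = 5.2e-10), and 19 of 21 MHC class I genes, with 2 not passed (adjusted p = 2.1e-10). Of 30 antiviral genes, 29 were lower and 1 higher (median log2 -1.59, adjusted p = 1.1e-31). Further calls were chemokines (18 higher, 3 lower and 5 not passed, adjusted p = 1.2e-07), checkpoint ligands (10, 3 and 3, adjusted p = 0.0043), NF-kB targets (13, 5 and 3, adjusted p = 0.00014), S phase (19, 2 and 9, adjusted p = 0.00041), glycolysis and hypoxia (19, 2 and 3, adjusted p = 1.5e-11) and tryptophan metabolism (8, 1 and 4, adjusted p = 0.00058). Calls without support from an estimated correlation were the receptors (7, 1 and 2, adjusted p = 0.011, and adjusted p = 0.061 with an estimated correlation), G2 and M phase (4, 14 and 12, adjusted p = 0.011, and adjusted p = 0.061 with an estimated correlation), cell death (16, 8 and 5, adjusted p = 0.045, and adjusted p = 0.061 with an estimated correlation), fibroblast and endothelial markers (2, 7 and 2, adjusted p = 0.034, and adjusted p = 0.084 with an estimated correlation) and mitochondrially encoded genes (10, 0 and 4, adjusted p = 2.0e-05, and adjusted p = 0.12 with an estimated correlation). The cell death call ended without 41BBL replicate 3 (adjusted p = 0.0514). Not called were the delivered genes (2, 1 and 0, adjusted p = 0.058), interferon gamma signalling (10, 10 and 1, adjusted p = 0.37), nucleic acid sensing (6, 5 and 4, adjusted p = 0.53), p53 targets (8, 7 and 6, adjusted p = 0.46), the stress response (12, 8 and 3, adjusted p = 0.13), cholesterol synthesis (9, 7 and 10, adjusted p = 0.54), epithelial genes (2, 2 and 2, adjusted p = 0.66), matrix genes (8, 14 and 4, adjusted p = 0.075), immediate early genes (6, 6 and 6, adjusted p = 0.30) and leukocyte markers (4, 1 and 3, adjusted p = 0.058). Adjusted over the list alone, the counts were 7 and 2 for receptors, 19 and 1 for MHC class I, 18 and 4 for chemokines, 20 and 4 for S phase, 4 and 16 for G2 and M phase, 10 and 7 for p53 targets, 13 and 8 for the stress response, 20 and 2 for glycolysis and 11 and 0 for mitochondrial genes, and for the other lists those given.

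In the called list of delivered genes with 41BBL the median was 0 while the mean was positive, because 1 of its 3 members rose. In some lists that camera did not call, the median, the mean and the test did not share 1 sign. These were interferon gamma signalling, epithelial genes and p53 targets with AAV-IFNG and AAV-4II against AAV-Vector, and MHC class II genes, chemokines and leukocyte markers with IL12B. With 41BBL they were MHC class II genes, cell death, the stress response, immediate early genes and fibroblast and endothelial markers. Between AAV-4II and AAV-IFNG they were immediate early genes and leukocyte markers, against IL12B interferon gamma signalling, G2 and M phase and immediate early genes, and against 41BBL interferon gamma signalling and nucleic acid sensing.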

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

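The offset for GC content and length, the thinning to the smallest total, the leaving out of single libraries for the list tests and all alternatives of the overlaps were chosen after seeing the data. The other alternatives were planned. Counts of changed genes and of called lists stayed within 1.5 times the reported value except where given here. DESeq2 gave 73 genes changed at least 2-fold with IL12B, 1 with 41BBL and 6 between AAV-4II and AAV-IFNG. No filter gave 39 such genes with 41BBL and 109 between AAV-4II and AAV-IFNG, the stricter filter 35 in the latter, and the GC and length offset 13 with 41BBL. For all changes with 41BBL, the run term gave 979 genes, thinning 871, the GC and length offset 667 and leaving out the 3 libraries out of number order 652. Between AAV-4II and AAV-IFNG these were 2560 with the run term, 2511 with thinning and 1808 without the 3 libraries. Thinning and leaving out libraries lower the depth or number of samples by construction. For the other settings the cause was not tested. Leaving out 1 library at a time gave 693 to 1413 genes with 41BBL, and 15 to 33 changed at least 2-fold. The overlap of IFNG and 41BBL in the same direction was 348 genes, 215 with the GC and length offset, 200 with thinning, 151 without the 3 libraries and 169 to 329 with 1 library left out.

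With an estimated correlation 7 lists were called with IL12B and 2 between AAV-4II and AAV-IFNG. fry, which asks a different question, called 24 lists with AAV-IFNG, 14 between AAV-4II and AAV-IFNG and 25 between AAV-4II and 41BBL. Over the 95 calls of single lists, 977 alternatives kept the call and 68 ended it, and none turned the direction of a call. Beside those in the report, calls ended with the replicate block for the G2 and M phase list (adjusted p = 0.0528 with IL12B and adjusted p = 0.0543 between AAV-4II and AAV-IFNG), leukocyte markers against IL12B (adjusted p = 0.0609) and cell death genes against 41BBL (adjusted p = 0.0501). The run term ended those of mitochondrially encoded genes with IL12B (adjusted p = 0.0989), the delivered genes with 41BBL (adjusted p = 0.0665), G2 and M phase between AAV-4II and AAV-IFNG (adjusted p = 0.0613) and leukocyte markers against IL12B (adjusted p = 0.052). fry did not call mitochondrially encoded genes with IL12B (adjusted p = 0.0799). Irf1 between AAV-4II and AAV-IFNG is given by level alone, since its change lies near 0 and turns sign between settings. The median log2 change of all genes stayed between -0.0353 and 0.0046 under the scalings tried. These scalings place the bulk of genes near 0 by construction, so this median cannot show that the results do not depend on the scaling. In simulated data 46% to 74% of 1.25-fold changes were found among genes of at least 1 CPM with AAV-Vector, so small changes can be missed.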

Other observations

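The test of osmotic response genes was written down before its result was seen. The other tests in this part were chosen after the results were seen. Akr1b3, Me1, Slc6a12 and the osmotic response genes named here fall outside the rule for named genes, and were picked for naming after their values were seen. A set of 52 genes, Il12b left out, rose at least 2-fold with both IL12B and AAV-IFNG against AAV-Vector, and 49 of them also rose with AAV-4II and 0 with 41BBL in the edgeR test. Akr1b3, an aldose reductase that makes sorbitol, stood at 617.8 ± 1.78 CPM with AAV-Vector, 1982 ± 33.2 with IL12B, 3717 ± 55.2 with AAV-IFNG, 2494 ± 46.6 with AAV-4II and 546 ± 4.97 with 41BBL. Me1, an enzyme that makes NADPH, stood at 95.4 ± 2.95 CPM with AAV-Vector, 198.3 ± 3.54 with IL12B and 247.9 ± 3.74 with AAV-IFNG. Slc6a12, a transporter of betaine, rose by log2 1.20 with IL12B and 2.02 with AAV-IFNG, and Csf1r by log2 1.70 and 4.06. Of the 123 genes at least 2-fold higher with IL12B, 63 were also called higher and 8 lower with AAV-IFNG, where independent lists would share 32.7 and 27.1, and 3.57 at least 2-fold higher with both. Both comparisons use the same AAV-Vector libraries, and simulations of unchanged groups that share their controls gave 0.15 genes called higher in both on average. No gene changes in those simulations, so hardly any passes the adjusted p. The real comparisons call many genes and so have a looser cutoff. The simulated number therefore cannot show how much noise in the shared libraries adds to the real overlap.

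The fall of type I antiviral genes with AAV-IFNG was weighed first. GC content and transcript length are argued against as the source, since with the offset for them the list median was log2 -1.78. A lower Ifnb1 transcript may contribute: the list was lower by over 2-fold in the median in the AAV-IFNG and AAV-4II groups, Ifnb1 was called lower in both, and 0 groups had the first without the second. With IL12B and 41BBL, Ifnb1 changed by log2 -0.29 ± 0.32 (adjusted p = 0.67) and -0.35 ± 0.31 (adjusted p = 0.58). Ifnb1 and the list fall in the same libraries, so an effect of less interferon beta cannot be told apart from another effect of delivered interferon gamma in this design, and the latter stays untested.

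The many small changes with 41BBL were weighed next, since their log2 values followed the GC content of genes (Spearman correlation -0.41 across 14693 genes, which are not independent replicates), as did those of AAV-4II against AAV-IFNG (-0.42). GC content and transcript length as the whole source are argued against by 480 of the 1486 genes that were called with the offset too. For the mitochondrially encoded genes they may be the source, since the offset ended the camera call (adjusted p = 0.62). The median log2 change of the edgeR fit went from 0.21 (quartiles 0.14 and 0.39) to 0.04 (quartiles -0.01 and 0.24). Vector replicate 3 as the only source of all these changes is argued against by 654 of the 1486 genes called without it as well. The other genes lost their call, which fewer libraries can also cause, so a part played by that library stays open. Leaving it out together with the offset was not tested. The antiviral list had a median of -0.15 with the offset (adjusted p = 8.2e-16), so an effect of 41BBL on it stays open as a hypothesis.

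The genes raised by both IL12B and AAV-IFNG were weighed last. Low levels in the shared AAV-Vector libraries are argued against by a median log2 difference of 1.29 between IL12B and 41BBL, which uses none of them. Carry-over of AAV-IFNG cells or libraries is argued against because Cd74, H2-Aa, H2-Ab1 and H2-Eb1 reached at most 0.0512% of their AAV-IFNG rise in IL12B, while the 52 genes reached 79.5% in the median. An osmotic stress response may contribute with IL12B. A list of 10 genes of that response, Akr1b3 and Slc6a12 left out, had a median log2 of 0.54, and 10 of 10 rose. The SE of the mean over these genes, which are not independent replicates, was 0.08. Without Hspa1b, Hspa4l and Hsph1, which also answer protein stress, the median was 0.39 over 7 genes, with an SE of the mean of 0.09. With AAV-IFNG the list was not tested, and its median was 0.17. There Hspa1b, Hspa4l and Hsph1 rose by log2 0.95, 1.05 and 0.74. Of the 7 other genes, Sgk1 and Slc38a2 rose by log2 0.18 and 0.21. The inositol transporter gene Slc5a3 and Nfat5 fell by log2 -0.63 and -0.07, and S100a4, Aqp1 and Slc6a6 did not pass. The AAV-IFNG side and other stresses therefore stay open.

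The comparisons of AAV-4II with AAV-IFNG and of 41BBL with AAV-Vector share no library. Across 15048 genes, their log2 changes correlated with r = 0.32, and with r = 0.25 after the offset for GC content and length. The changes of AAV-4II against AAV-IFNG and of IL12B against AAV-Vector gave r = -0.05 with and without it. The delivered genes were among the 15048. Tnfsf9 rose by log2 9.16 and 9.88 in the first pair of comparisons, and Il12b by log2 7.36 and 11.06 in the second. No r was computed without them, so these values cannot show how far the other genes moved together.

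The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For all 21 counts of the 7 comparisons, the real split was the 1 with the largest value. Every other split mixes both treatments within each group, so the treatment difference enters the spread and lowers the number of called genes. Such splits also keep a part of the difference between their groups. Their values are therefore not those of unchanged groups, and give no rate of false calls for genes or lists. The real and highest other numbers of changed genes were 8712 and 0 for AAV-IFNG, 1907 and 1 for IL12B, 1486 and 1 for 41BBL and 8004 and 0 for AAV-4II against AAV-Vector. For AAV-4II they were 4042 and 11 against AAV-IFNG, 7981 and 0 against IL12B and 8516 and 1 against 41BBL. In the same order of comparisons, changes of at least 2-fold numbered 1138 and 0, 140 and 1, 21 and 0, 952 and 0, 65 and 5, 1028 and 0, and 1003 and 0. Called lists numbered 12 and 8, 15 and 6, 11 and 4, 18 and 11, 7 and 3, 17 and 13, and 15 and 10.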
